A study of Mus musculus with 12 samples.

How the data were processed

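Oviducts of ICR mice were sampled at proestrus, estrus, metestrus and diestrus, with 3 arrays per stage and 12 in all. Total RNA was column-purified with a DNase step, its quality was read on a Bioanalyser, and biotin-labelled cRNA was hybridised to a 1-colour Illumina bead array. The labels number the arrays of each stage 1 to 3 and do not say whether these are separate animals, pools or repeated hybridisations, nor whether the numbers pair arrays across stages.

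Per the file headers, each array comes with a raw intensity and a detection p-value for each of the 25697 probes. The raw intensities had no background subtracted, since their lowest values lie above 50. The deposited matrix holds intensity values on a linear scale that the authors had background-subtracted and quantile normalized, so 21.2% to 24.9% of its values per array are negative. The distributions in it are equal within replicate 1 (4 arrays, median 46.7 to 46.8) and within replicates 2 and 3 (8 arrays, median 23.4), and differ between these sets. The authors therefore appear to have normalized the sets apart. The raw and the deposited values had a rank correlation of 1 on the replicate 1 arrays and of 0.971 to 0.972 on the others. The software used for this is not given in the sources used here.

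The raw intensities were background-corrected with normexp guided by the detection p-values, quantile normalized over all 12 arrays and put on the log2 scale with an offset of 16 (neqc, limma 3.58.1, R 4.3.3). Probes were kept when the detection p was under 0.01 on at least 3 of the 12 arrays, which left 14778. Gene names came from the symbols listed for the platform, where 23978 probes had 1 symbol, 1719 had none and 0 had several. Of the named probes, 23962 had an Entrez identifier that matched the gene identifiers supplied and 16 did not. For a gene with several kept probes (2717 genes), the probe with the highest mean was used, and the 837 kept probes without a name were left out. That left 10144 genes of the 16593 on the array. At or above an intensity of 65000, near the scanner's ceiling, there were 7 values.

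Median raw intensity was 139 to 156 on replicate 1 arrays and 99.3 to 105 on the others. The lowest probe value per array was 52.3 to 57.9, and 48.6% to 58.1% of probes per array were detected. Many genes thus lie close to background, where fold differences are compressed. For a gene with no detected probe on any array of a stage, the difference is given as "at least" a value. It was computed by raising its intensities there to the lowest level at which probes were detected on that array.

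A linear model with 1 mean per stage was fitted with limma to the 12 arrays without a block, leaving 8 residual degrees of freedom, and errors were moderated with eBayes. A moderated F test asked which genes changed across the cycle. The 6 pairs of stages were then compared, 4 in the order of the cycle and 2 across it. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Standard errors are those of the moderated fit on the log2 scale. Genes named in the comparisons were chosen by a rule: up to 8 of the largest rises and falls among called genes with non-overlapping arrays in successive stages, and up to 4 across the cycle, leaving out clone names. Esr1, Pgr and Ovgp1 are named whatever their result.

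Before the data were examined, 29 gene lists were written from general knowledge, covering hormone response, epithelial function, defence, matrix and metabolism, and markers of other cell types. Each list with at least 5 tested genes, 28 in all, was tested in each comparison with camera (limma, preset correlation 0.01), and the 168 p-values were adjusted together. A list result is a camera call, described by the median log2 difference of its members and by how many passed on their own. Up to 4 members per list with the lowest F p-values are named, or 2 where none passed. Counts adjusted over the list alone adjust the p-values of a list's members among themselves. A list median with bounds puts the "at least" value in place of the fitted one for undetected genes. Members without a kept probe left the lists, as in the oocyte list, with 22 named genes on the array and 15 tested. None of these lists was tested without the detection filter.

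The pairing of arrays by replicate number was checked after removing the mean of each stage. Correlations between arrays of different stages were 0.62 to 0.81 within replicate 1, 0.26 to 0.51 within replicate 2 and 0.36 to 0.55 within replicate 3, against 0.22 to 0.54 between replicate 2 and replicate 3 of different stages. The number thus carries the difference between the array sets, and little shows that it pairs replicates 2 and 3. The fit without a block was kept as planned. Among the 5072 genes of higher mean, log2 differences between replicates 2 and 3 had an SD of 0.12 to 0.14 at proestrus, estrus and metestrus and of 0.23 at diestrus, against 0.33 to 0.55 between replicate 1 and the others. Over 1.5-fold lay 0.0197% to 0.0591% of genes in those 3 stages and 1.46% at diestrus, against 7.02% to 26.5% for pairs with replicate 1. If replicates 2 and 3 were repeats of one sample, the counts from these 2 alone would rest on measurement error and not on differences between animals.

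The method was tested on simulated data with 200 of 10144 genes changed, in 5 runs. Without a block, 15.3% of genes changed 1.5-fold were recovered, 56.6% of those changed 2-fold and 94.7% of those changed 4-fold, and 0.367% of the calls were false. With the replicate block these were 53.3%, 89.3% and 99.7%, with 5.33% false. In this simulation the fit without a block therefore missed many changes below 2-fold. The simulated set difference of a gene was the same in every stage, as the block assumes. On the real arrays, pairs with replicate 1 differed by an SD of 0.54 to 0.55 at metestrus and 0.33 to 0.38 at the other stages. The simulated rates may therefore not hold for these arrays. A simulated list of 20 genes shifted by 0.5 had a camera p of 4.2e-37, and 4 of 100 lists without a shift had a p under 0.05. These lists were drawn with independent genes and no difference between the array sets. They therefore do not test camera on genes that move together, as members of the real lists may.

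Alternatives written down before the files were opened were quantile-normalized raw intensities, normexp without detection p-values, scaling to a common median, the deposited values (log2, floored at 16), no detection filter, detection on all arrays (8315 genes), all kept probes, the mean of a gene's probes and the replicate number as a block. Array weights, a variance trend with a robust prior, each array left out in turn and only the 6 arrays of the stages compared completed the plan. For the lists an estimated correlation and fry were added. The chip as a block was planned but not run, since the files name no chip. After the data were seen, 4 more were added: the array set as a block, replicates 2 and 3 alone (for the counts and for the lists), and the deposited values with the replicate block. Distances between arrays are 1 minus the Pearson correlation of log2 intensities. Groupings of the arrays were drawn 100 times for the whole cycle, and each pair of stages allows 10 splits of its 6 arrays. Tables were handled with the data.table package (version 1.17.8) and figures drawn with matplotlib 3.10.9 under Python 3.11.15.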

Results

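The oviducts of ICR mice, an outbred stock, were sampled at 6 weeks of age in the 4 stages of the estrous cycle. RNA was measured on a 1-colour Illumina bead array carrying 25697 probes, with 3 arrays each for proestrus, estrus, metestrus and diestrus and 12 arrays in all. The question the design puts is which genes are expressed differently between stages of the cycle, around ovulation and away from it. The arrays of replicate 1 were brighter than the others, with a median probe intensity of 139 to 156 against 99.3 to 105 for replicates 2 and 3. Replicate 1 also had more detected probes, 55.6% to 58.1% against 48.6% to 51.8%. After filtering, 10144 genes were tested, and 3 arrays per stage set the precision. Fold differences below come from a limma fit to all 12 arrays, each error is a standard error on the log2 scale, and n = 3 arrays per stage throughout. The labels do not say whether replicates were separate animals, pools or repeated hybridisations of one sample, so the p-values measure only the spread between these arrays.

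Across the whole cycle, 545 of the 10144 genes changed (moderated F, adjusted p under 0.05), which is 5.37% of those tested. The progesterone receptor gene Pgr was highest at proestrus, with a mean log2 intensity of 8.58, and lay at 7.80 at estrus, 7.77 at metestrus and 7.35 at diestrus (limma moderated F, adjusted p = 0.0017). The estrogen receptor gene Esr1 ranged only from 11.11 to 11.30 between stages and did not pass (limma moderated F, adjusted p = 0.9996). Ovgp1, which encodes oviductin, the main glycoprotein that oviduct secretory cells release, had means between 15.06 and 15.18 and did not pass either (limma moderated F, adjusted p = 0.9996). Its values on single arrays, 14.8 to 15.8, lie near the top of the measured range, where differences may be compressed. The water channel gene Aqp8 and the progesterone-inactivating enzyme gene Akr1c18 had the lowest p-values among the genes named here, each with an adjusted F p of 1.8e-07. With the replicate number as a block, 1659 genes changed, and the 545 were all among them. In replicates 2 and 3 alone the count was 1082, and from the deposited values without a block it was 67. Leaving out proestrus replicate 2 gave 345 genes and leaving out proestrus replicate 3 gave 351.

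Of the 545 genes, 174 (31.9%) were highest at proestrus, 137 (25.1%) at estrus, 127 (23.3%) at metestrus and 107 (19.6%) at diestrus. The lowest stage was proestrus for 239, metestrus for 161, diestrus for 118 and estrus for 27. The commonest pairs of highest and lowest stage were metestrus over proestrus with 105 genes, proestrus over metestrus with 102 and diestrus over proestrus with 97. Of 100 groupings of the arrays, drawn without regard to the array sets and the real one included, 88 gave at least as large a largest share. Each share was taken over the 545 genes of lowest F p-value, although most of the other groupings called no genes. This comparison therefore cannot tell whether the largest share stands out. The shares of lowest stages were not tested. With the replicate block the shares were 30.2%, 19.65%, 27.19% and 22.97%. The deposited values without a block put 58.2% of their called genes at estrus and 2.99% at diestrus.

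The arrays parted by array set before they parted by stage. The first principal component held 42.8% of the variance and separated replicate 1 from replicates 2 and 3. The second component held 23.8%, with the proestrus and estrus arrays above and the metestrus and diestrus arrays below. Correlation distances between stages were 1.202 times those within stages, and 15 of 100 groupings of the arrays, the real one included, gave a ratio as high. The groupings were drawn without regard to the array sets. Each other grouping with as high a ratio put 2 or 3 replicate 1 arrays in a group, unlike the real one. That count therefore cannot be read against chance. After the difference between the array sets was removed, the ratio was 2.16. It was 2.38 with the replicate block. When each replicate was centred on its own mean, the ratio was 2.43, and no other of 100 shuffles of the stages within replicates exceeded 1.76. Leaving out metestrus replicate 1, 2 or 3 gave ratios of 1.32, 1.28 and 1.29.

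**Figure D1:**
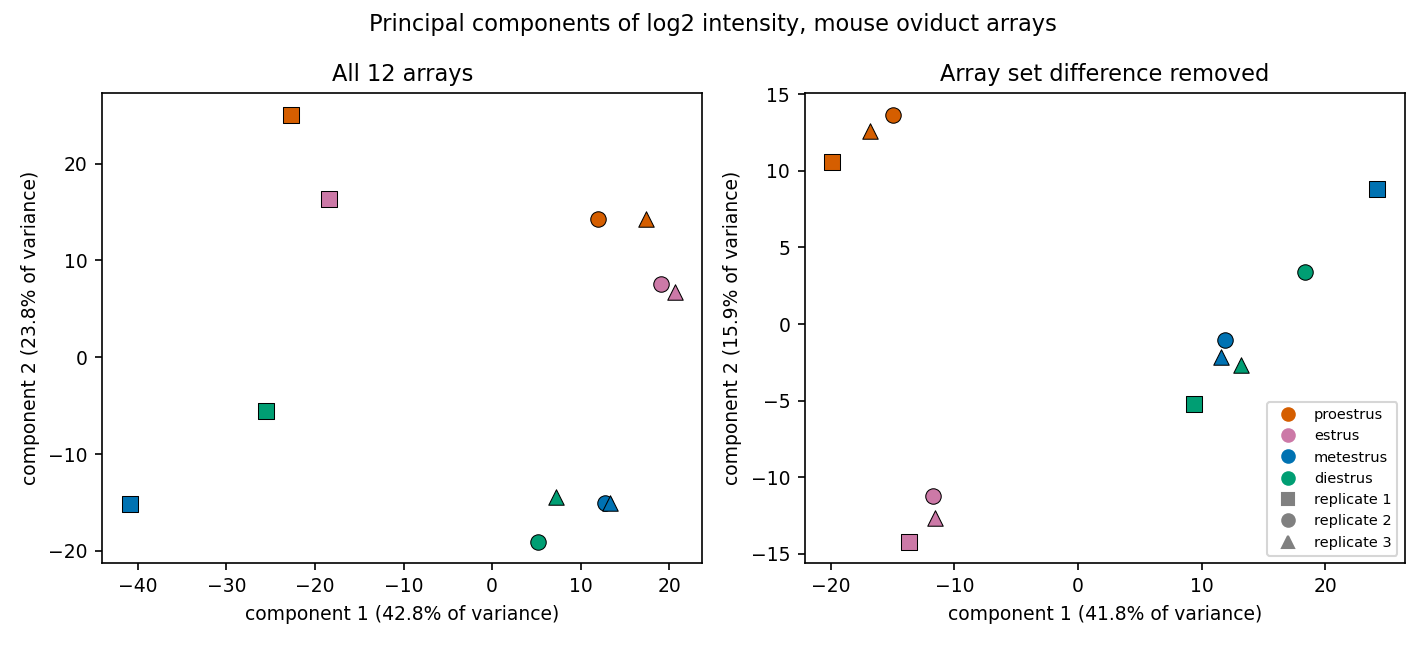
Scores of the 12 arrays on the first 2 principal components of the log2 intensities of the tested genes, before (left) and after (right) removing the difference between the array sets; colour gives the stage and the symbol the replicate. The first component holds 42.8% of the variance and parts replicate 1 from the rest on the left, and holds 41.8% and parts proestrus and estrus from metestrus and diestrus on the right.

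From proestrus to estrus, the step that spans ovulation, 87 genes rose and 16 fell, and oocyte and ovarian markers were among those that rose. Akr1c18 was 14.96-fold higher at estrus (log2 difference 3.90 ± 0.15, adjusted p = 1.1e-07). Prss35, a member of the serine protease family, was 10.3-fold higher (3.37 ± 0.18, adjusted p = 1.6e-06), and Mgarp, which encodes a mitochondrial protein, was 7.46-fold higher (2.90 ± 0.18, adjusted p = 3.7e-06). Padi6, a gene of the oocyte cytoplasm, was not detected at proestrus and was at least 5.39-fold higher at estrus, and Defb19, a beta-defensin gene, was likewise at least 4.90-fold higher. Among the genes that fell, Ccl11, the eosinophil attractant, was 2.33-fold lower (SE 0.14, adjusted p = 7.7e-04), Aqp8 2.06-fold lower (SE 0.12, adjusted p = 0.0011) and Lrat, which esterifies retinol, 1.84-fold lower (SE 0.13, adjusted p = 0.0059).

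Other large rises at estrus were those of Prap1, a secreted proline-rich protein gene (6.13-fold), Sprr2d, a cornified envelope gene (at least 4.05-fold), and Mup2 (10.9-fold). The probes for Mup2 and for Sprr2d belong to families of near-identical genes, so which member they report is uncertain, and a second Mup2 probe rose by 1.29 on the log2 scale against 3.45 for the first. Among the genes that fell were Rem2, a small GTPase gene (2.44-fold lower), Ramp3, a co-receptor gene (2.15-fold), and Cyth4, an exchange factor of small GTPases (2.02-fold). Zfp985, a zinc finger gene, was at least 1.49-fold lower at estrus, where it was not detected. Padi2, a peptidylarginine deiminase gene, was 1.82-fold lower (adjusted p = 0.023). The call of Ramp3 was lost when proestrus replicate 2 (adjusted p = 0.051) or 3 (0.057) was left out and when its 3 probes were averaged (0.078). That of Padi2 was lost without estrus replicate 1 (0.099) or 2 (0.114) or proestrus replicate 2 (0.091) or 3 (0.128).

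Of 15 tested oocyte genes, 9 rose from proestrus to estrus and 6 did not pass, with a list median of 1.53 on the log2 scale, or 0.98 with undetected genes at their bound (camera adjusted p = 6.9e-28). The rise was 2.24 ± 0.19 for Nlrp14 and 2.38 ± 0.27 for Ooep, both of which act in the egg and early embryo. Of 15 ovarian granulosa, theca and luteal cell genes, 8 rose and 7 did not pass, with a median of 1.21, or 0.62 with bounds (camera adjusted p = 1.5e-24). Inha, the inhibin alpha subunit, rose by 1.81 ± 0.20, and Cyp11a1, which starts steroid synthesis from cholesterol, by 2.46 ± 0.13. A probe was kept when detected on 3 arrays, the number in 1 stage, so genes seen at estrus alone stayed in. Of the tested genes, 12 oocyte and 13 ovarian ones were detected on all estrus arrays, against 4 and 8 on all proestrus arrays. Counts, medians and p-values of both lists therefore partly restate the filter, as in other comparisons with estrus. With detection on all arrays the ovarian list kept its call and the oocyte list was not tested. The innate defence and complement list was also higher at estrus, with a median of 0.27 over 22 genes (camera adjusted p = 1.4e-05), and 1 member, the protease inhibitor Slpi, passed on its own at 1.24 ± 0.24. These 3 list results held with an estimated correlation. Over the camera and fry alternatives the highest adjusted p was 0.0019 for the oocyte list, 0.0019 for the ovarian list and 0.012 for innate defence. The very small p-values above therefore depend on the setting of the test. Over the alternatives tried the oocyte median ran from 0.62 to 1.60 and the ovarian one from 0.47 to 1.80, both lowest for raw intensities without background correction. Of the other marker lists at this step, neutrophil genes had a median of 0.33, given below. The lists that did not pass had medians of 0.02 for adipocyte, 0.05 for mesothelium, 0.02 for endothelium, -0.02 for macrophage, -0.02 for smooth muscle, -0.01 for lymphocyte and -0.23 for erythrocyte genes.

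Beside these marker shifts, the cell cycle list was higher at estrus with a median of 0.19 (camera adjusted p = 0.0044, but adjusted p = 0.22 with an estimated correlation), with 0 of 25 members past the test. The neutrophil list had a median of 0.33 (camera adjusted p = 1.9e-04, but adjusted p = 0.21 with an estimated correlation) and the interferon response list one of 0.13 (camera adjusted p = 0.038, but adjusted p = 0.11 with an estimated correlation), each with 0 members past the test. The cholesterol biosynthesis list was lower, with a median of -0.16 (camera adjusted p = 0.020, but adjusted p = 0.084 with an estimated correlation), again with 0 members past the test. The interferon call was lost without diestrus replicate 1 (adjusted p = 0.052), estrus replicate 2 (0.14) or 3 (0.062) or proestrus replicate 3 (0.12), and the cholesterol call without proestrus replicate 1 (0.094). Estrogen-induced genes had no list result at this step, with 3 of 19 lower (Pgr, Padi2 and Ramp3) and 1 higher, the chloride channel regulator Clca1.

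In all, 103 genes differed between estrus and proestrus, 87 higher and 16 lower at estrus. The count was 310 (225 higher, 85 lower) with the replicate block, 186 in replicates 2 and 3 alone and 31, all higher, from the deposited values without a block. It was 57 without estrus replicate 2, 59 without estrus replicate 3 and 64 without proestrus replicate 3.

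From estrus to metestrus, 180 genes fell and 70 rose, and Mgarp, Prss35, Sprr2d and Defb19, which had risen at estrus, were among those that fell. Inha was 13.02-fold lower at metestrus (SE 0.20, adjusted p = 1.2e-06), Hsd17b1, which makes estradiol from estrone, 12.8-fold lower (SE 0.28, adjusted p = 1.7e-05) and Mgarp 12.1-fold lower (SE 0.18, adjusted p = 1.2e-06). Whether Hsd17b1, Mgarp and other genes that peaked at estrus changed in oviduct cells or with the ovarian markers was not tested. Prss35 was 10.8-fold lower, the aldo-keto reductase gene Akr1cl 7.92-fold lower (log2 differences of -2.99 and -1.98 by its 2 probes), Sprr2f 7.63-fold lower and Defb19 and Sprr2d, undetected at metestrus, at least 5.20-fold and 4.302-fold lower. Cyp2j11, a cytochrome P450 gene undetected at estrus, was at least 6.71-fold higher at metestrus, and the chloride channel gene Ano2 at least 2.87-fold higher. Pga5, a pepsinogen gene, was 4.25-fold higher (SE 0.28, adjusted p = 0.0016).

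Smaller rises at metestrus were those of Il17rb, the receptor of interleukin 25 (2.97-fold), Serpina1d, of the alpha-1-antitrypsin family (2.95-fold), and Tmem158 (2.59-fold). Slc5a11, a sodium-coupled inositol transporter, was also higher and was detected on 1 of 3 estrus arrays. Gldc, of the glycine cleavage system, was undetected at estrus and at least 1.84-fold higher. Serpina1d and Sprr2f are also members of near-identical families.

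The oocyte list was lower at metestrus than at estrus, with 9 of 15 genes lower and a median of -1.53, or -1.18 with bounds (camera adjusted p = 2.3e-14). The ovarian list moved likewise, with 8 of 15 lower and a median of -1.27, or -0.69 with bounds (camera adjusted p = 3.8e-18). Of 18 cholesterol biosynthesis genes, 2 fell and 16 did not pass alone, with a median of -0.54 (camera adjusted p = 4.8e-10). Fdps, which makes farnesyl diphosphate, fell by 1.09 ± 0.13 on the log2 scale. Of 19 estrogen-induced genes, 5 fell and 1 rose, with a median of -0.23 (camera adjusted p = 6.3e-06), among them Aqp5, a water channel, which fell by 0.92 ± 0.13, and Padi2, which fell by 1.14 ± 0.16. Of 25 cell cycle genes, 3 fell, with a median of -0.41 (camera adjusted p = 3.4e-08), and Birc5, an inhibitor of apoptosis that acts in mitosis, fell by 1.02 ± 0.21. Of 20 genes of steroid receptors and steroid metabolism, 4 fell, with a median of -0.15 (camera adjusted p = 0.0012). All 6 held with an estimated correlation. Over the camera and fry alternatives the highest adjusted p was 0.011 for oocyte, 0.0019 for ovarian and 0.0019 for cholesterol genes. It was 0.029 for estrogen-induced, 0.043 for cell cycle and 0.029 for steroid genes. Over the alternatives the oocyte median ran from -1.64 to -0.64 and the ovarian one from -1.73 to -0.51.

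Other lists passed at this step only with the preset correlation. The neutrophil list had a median of -0.54 with 3 of 14 lower (camera adjusted p = 1.5e-04, but adjusted p = 0.20 with an estimated correlation), and Lcn2, an iron-scavenging protein gene, was 2.83-fold lower. The interferon list had a median of -0.25 with 1 of 21 lower, Isg15 (camera adjusted p = 0.011, but adjusted p = 0.061 with an estimated correlation). For adipocyte genes the median was -0.42 with 1 of 11 lower, Cidec (camera adjusted p = 0.013, but adjusted p = 0.088 with an estimated correlation). For ion and water transport it was -0.14 with 4 of 21 lower, among them Aqp8 and the anion exchanger Slc26a4 (camera adjusted p = 0.045, but adjusted p = 0.30 with an estimated correlation). The progesterone-induced list was higher, with a median of 0.09 and 3 of 11 genes up (camera adjusted p = 0.038, but adjusted p = 0.15 with an estimated correlation), and among them the glucocorticoid-induced gene Tsc22d3 rose by 0.74 ± 0.11 and the transcription factor gene Gata2 by 0.66 ± 0.13. The median of that list ran from 0.08 to 0.33 over the alternatives. The last 2 list results were lost with the replicate block, at adjusted p = 0.082 for ion and water transport and 0.062 for the progesterone-induced list. The progesterone-induced call was also lost without metestrus replicate 1 (adjusted p = 0.12) or estrus replicate 2 (0.11). The ion and water transport call was lost without metestrus replicate 1 (0.11), 2 (0.071) or 3 (0.053) or estrus replicate 2 (0.066) or 3 (0.068).

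In all, 250 genes differed between metestrus and estrus, 70 higher and 180 lower at metestrus. The count was 847 (372 higher, 475 lower) with the replicate block, 475 in replicates 2 and 3 alone and 53 (5 higher, 48 lower) from the deposited values without a block. It was 147 without estrus replicate 2, 152 without estrus replicate 3 and 98 when the fit used only the 6 arrays of these stages.

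From metestrus to diestrus, only 7 genes differed. Akr1c18 was 3.25-fold lower at diestrus (SE 0.15, adjusted p = 0.0011), H2-Ea, a class II histocompatibility gene, 3.51-fold lower (SE 0.25, adjusted p = 0.021) and Serpina1d 1.79-fold lower (SE 0.11, adjusted p = 0.018). Gulo, which completes vitamin C synthesis, was 2.04-fold higher (SE 0.12, adjusted p = 0.011), and Hsd17b7, a reductase of cholesterol synthesis and estradiol formation, 2.34-fold higher (SE 0.17, adjusted p = 0.021). H2-K1, a class I histocompatibility gene, was 2.15-fold higher (SE 0.15, adjusted p = 0.021) and Mup2 2.70-fold higher (SE 0.19, adjusted p = 0.018), but second probes for these genes gave log2 differences of 0.21 and 0.13, so both depend on the probe. The H2 genes are likewise a family of similar genes, and which member the probes for H2-Ea and H2-K1 report is uncertain.

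As a group, 21 interferon response genes were higher at diestrus than at metestrus, with a median of 0.36 (camera adjusted p = 2.3e-14), although 0 passed alone over all genes and 5 did so adjusted over the list alone. The oocyte list was higher too, with a median of 0.42, or 0.37 with bounds, and 0 of 15 past the test (camera adjusted p = 8.7e-09), and it ran from 0.16 to 0.61 over the alternatives. The extracellular matrix list was lower, with a median of -0.17 over 30 genes (camera adjusted p = 2.1e-05), as was the erythrocyte list, with a median of -0.58 over 5 genes (camera adjusted p = 1.5e-04). The erythrocyte fall was uneven, with medians of -0.02, -1.22 and -0.40 in replicates 1, 2 and 3 and of -0.94 to -0.22 over the alternatives tried. These 4 held with an estimated correlation, and 0 members of the last 2 passed alone. Over the camera and fry alternatives their highest adjusted p was 0.0019 for interferon, 0.027 for oocyte, 0.046 for matrix and 0.028 for erythrocyte genes.

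The remaining list results of this step were small and passed only with the preset correlation, with 0 members past the test in each. Motile cilia genes had a median of 0.12 (camera adjusted p = 0.0044, but adjusted p = 0.15 with an estimated correlation) and secretory epithelium genes one of 0.11 (camera adjusted p = 0.044, but adjusted p = 0.13 with an estimated correlation). Endoplasmic reticulum chaperones had a median of -0.16 (camera adjusted p = 0.0044, but adjusted p = 0.46 with an estimated correlation). Retinoid genes had one of -0.13 (camera adjusted p = 0.020, but adjusted p = 0.084 with an estimated correlation) and endothelium genes one of -0.13 (camera adjusted p = 0.023, but adjusted p = 0.27 with an estimated correlation). The neutrophil list, at 0.14 (camera adjusted p = 0.039, but adjusted p = 0.47 with an estimated correlation), was lost with the replicate block (adjusted p = 0.064). Without metestrus replicate 1 the chaperone list had a median of 1.3e-04 (adjusted p = 0.97) and the neutrophil list was lost at the same adjusted p, with cilia lost at 0.25 and retinoid genes at 0.16. Other arrays whose omission ended a call were diestrus replicate 1 (secretory 0.26, neutrophil 0.083, endothelium 0.32), metestrus replicate 2 (secretory 0.22, retinoid 0.058, endothelium 0.18) and diestrus replicate 2 (chaperones 0.089, retinoid 0.094). Metestrus replicate 3 (secretory 0.083, endothelium 0.12) and diestrus replicate 3 (secretory 0.069, chaperones 0.098, neutrophil 0.16) did so too.

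Of the 7 genes, 4 were higher and 3 lower at diestrus, and 306 genes had an unadjusted p under 0.05. The count was 30 (18 higher, 12 lower) with the replicate block, 9 in replicates 2 and 3 alone and 0 from the deposited values without a block in limma, where 54 had an unadjusted p under 0.05. With the arrays scaled to a common median, 3 were higher and 4 lower. It was 1 without metestrus replicate 2 or diestrus replicate 2, 2 without diestrus replicate 1 or 3, 4 without metestrus replicate 3 and 13 without metestrus replicate 1. Akr1c18 alone stayed past the threshold whichever array was left out. The highest adjusted p with 1 array left out was 0.12 for Mup2 (without diestrus replicate 1), 0.12 for Hsd17b7 (diestrus 3), 0.15 for H2-K1 (diestrus 1), 0.072 for Gulo (metestrus 2), 0.15 for H2-Ea (diestrus 1) and 0.10 for Serpina1d (diestrus 1). In replicates 2 and 3 alone Mup2 (adjusted p = 0.068), H2-K1 (0.103) and Serpina1d (0.057) did not pass.

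**Figure D2:**
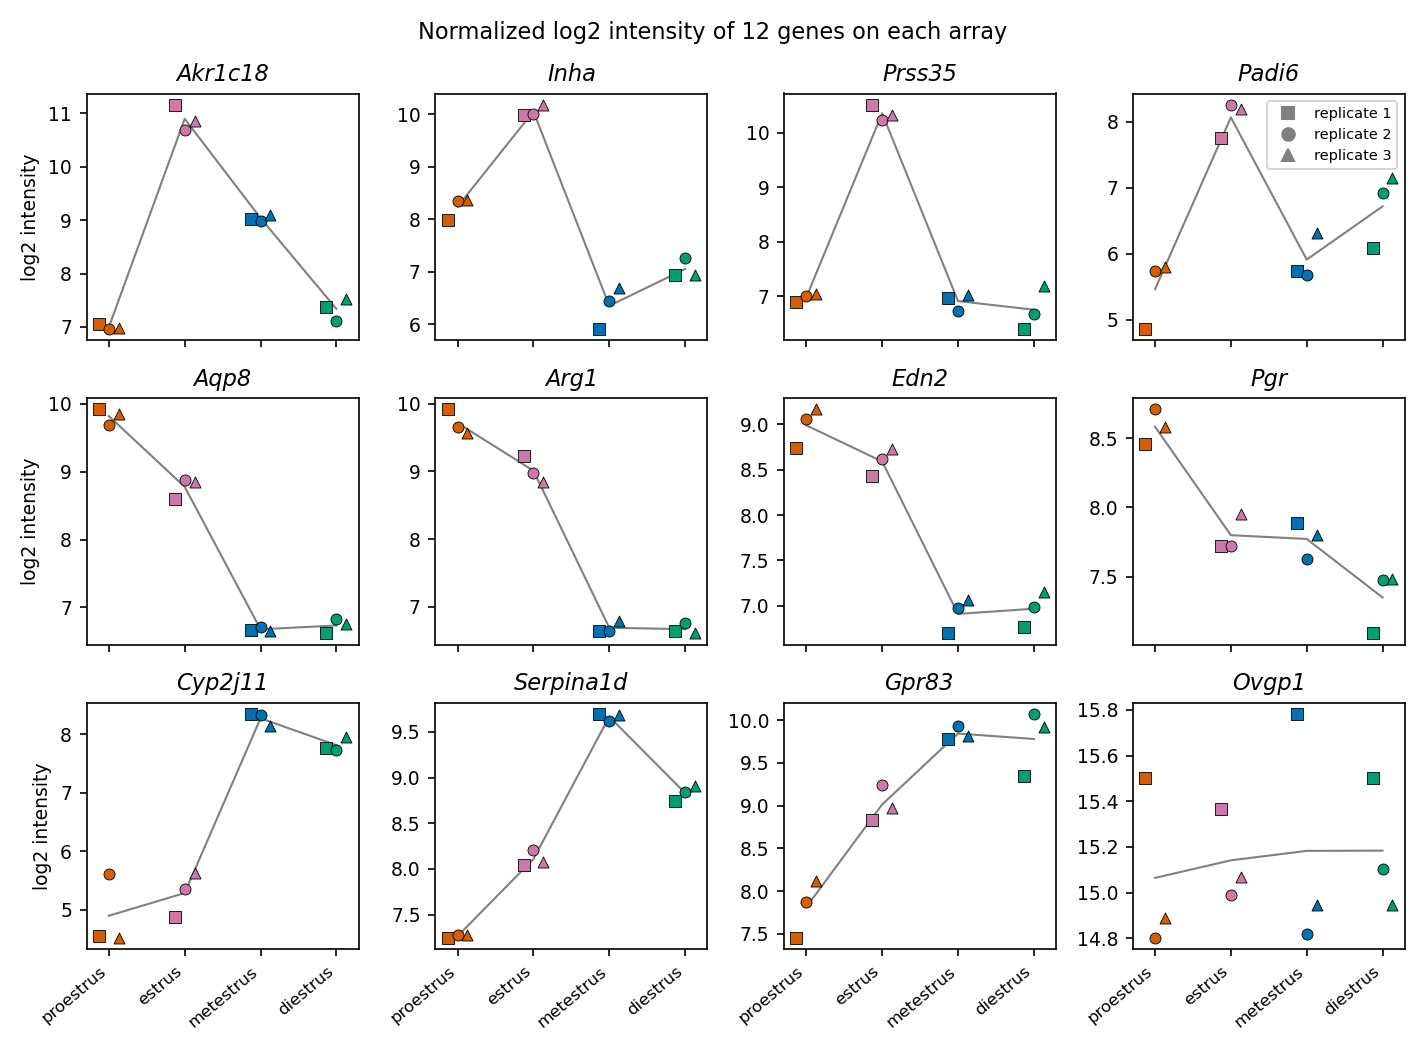
Normalized log2 intensity (vertical axis) of 12 genes in each stage (horizontal axis); each point is 1 array, the symbol gives the replicate and the line joins the stage means. Akr1c18 rises 14.96-fold from proestrus to estrus, Aqp8 and Arg1 fall from proestrus to metestrus, and Ovgp1 differs more between replicates than between stages.

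From diestrus to proestrus, the step into the estrogen-dominated part of the cycle, the estrogen-induced and cholesterol biosynthesis lists rose, and Aqp8 and Arg1 had the largest rises of single genes. Aqp8 was 8.49-fold higher at proestrus (3.09 ± 0.12, adjusted p = 2.0e-07) and Arg1, the urea cycle arginase, 8.24-fold higher (3.04 ± 0.14, adjusted p = 4.4e-07). Edn2, which encodes the smooth muscle constrictor endothelin 2, was 4.06-fold higher (2.02 ± 0.16, adjusted p = 3.8e-05), and Inhba, the activin beta A subunit, 4.22-fold higher (2.08 ± 0.22, adjusted p = 2.3e-04). Cyp2j11, undetected at proestrus, was at least 4.54-fold lower, and Cyp2f2, also a cytochrome P450 gene, 3.46-fold lower (SE 0.14, adjusted p = 2.9e-05). The orphan receptor gene Gpr83 was 3.90-fold lower (SE 0.21, adjusted p = 2.8e-04) and the Wnt receptor gene Fzd10 was lower too (adjusted p = 1.5e-04), by -1.93 for a probe detected on 1 of 3 proestrus arrays and by -0.79 for its second probe.

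Also higher at proestrus were Padi2 (4.51-fold), the carbonic anhydrase gene Car12 (4.10-fold), Cdsn, a corneodesmosome gene (4.05-fold), and Prss29, a serine protease gene (3.99-fold). Lgi1, a secreted leucine-rich repeat protein gene, was lower by a probe not detected at proestrus, and Ano2 was at least 1.68-fold lower. Mup2 was 6.14-fold lower and H2-K1 3.94-fold lower by the probes used, whereas their second probes gave log2 differences of -0.18 and -0.46.

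Of 19 estrogen-induced genes, 8 were higher at proestrus, 1 was lower and 10 did not pass, with a median of 0.54 (camera adjusted p = 3.9e-07). Aqp5 was higher by 1.71 ± 0.13, Ramp3 by 1.84 ± 0.18 and the growth factor gene Igf1 by 1.30 ± 0.16. Of 18 cholesterol biosynthesis genes, 6 were higher and 12 did not pass, while 13 were higher and 1 lower adjusted over the list alone, with a median of 0.63, or 0.54 with bounds (camera adjusted p = 1.7e-10). Fdps was higher by 1.31 ± 0.13, the lanosterol synthase gene Lss by 0.84 ± 0.14 and the demethylase gene Cyp51 by 1.06 ± 0.22. Erythrocyte genes had a median of 0.96 over 5 genes with 1 higher (camera adjusted p = 2.8e-04), and that 1 was Tmod1, an actin filament capping gene also known from muscle, at 1.47 ± 0.13. That median ran from 0.42 to 1.11 over the alternatives. The interferon list was lower at proestrus, with a median of -0.32 and 2 of 21 genes lower (camera adjusted p = 0.0054), and Rsad2, an antiviral gene, had a log2 difference of -1.11 ± 0.15. These 4 held with an estimated correlation. Their highest adjusted p over the camera and fry alternatives was 0.027 for estrogen-induced, 0.0019 for cholesterol, 0.027 for erythrocyte and 0.046 for interferon genes.

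The oocyte list was lower at proestrus than at diestrus, with a median of -0.69, or -0.29 with bounds, and 6 of 15 genes lower (camera adjusted p = 6.3e-06, but adjusted p = 0.061 with an estimated correlation), and it ran from -0.77 to -0.28 over the alternatives. The cell cycle list had a median of 0.34 with 2 of 25 higher (camera adjusted p = 1.5e-04, but adjusted p = 0.13 with an estimated correlation). For steroid receptors and steroid metabolism the median was 0.27, with 6 of 20 higher and 1 lower (camera adjusted p = 0.0090, but adjusted p = 0.058 with an estimated correlation), and Pgr was higher by 1.23 ± 0.14. That steroid result was also lost when genes had to be detected on all arrays, with a median of 0.01 (adjusted p = 0.20). For innate defence and complement it was -0.21 with 3 of 22 lower and 1 higher (camera adjusted p = 0.025, but adjusted p = 0.088 with an estimated correlation), a call lost without diestrus replicate 1 (adjusted p = 0.12) or proestrus replicate 2 (0.062). Progesterone-induced genes had no list result here, but Hsd11b2, which inactivates glucocorticoids, was higher at proestrus (detected on 3 of 3 arrays there and on 1 of 3 at diestrus), while Tsc22d3 and Fkbp5, a chaperone of steroid receptors, had log2 differences of -0.84 ± 0.11 and -0.94 ± 0.14.

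In all, 493 genes differed between proestrus and diestrus, 224 higher and 269 lower at proestrus. The count was 1649 (705 higher, 944 lower) with the replicate block, 1292 in replicates 2 and 3 alone and 20 (13 higher, 7 lower) from the deposited values without a block. It was 266 without proestrus replicate 2, 270 without diestrus replicate 2, 283 without proestrus replicate 3, 292 without diestrus replicate 3 and 793 without metestrus replicate 1.

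**Figure D3:**
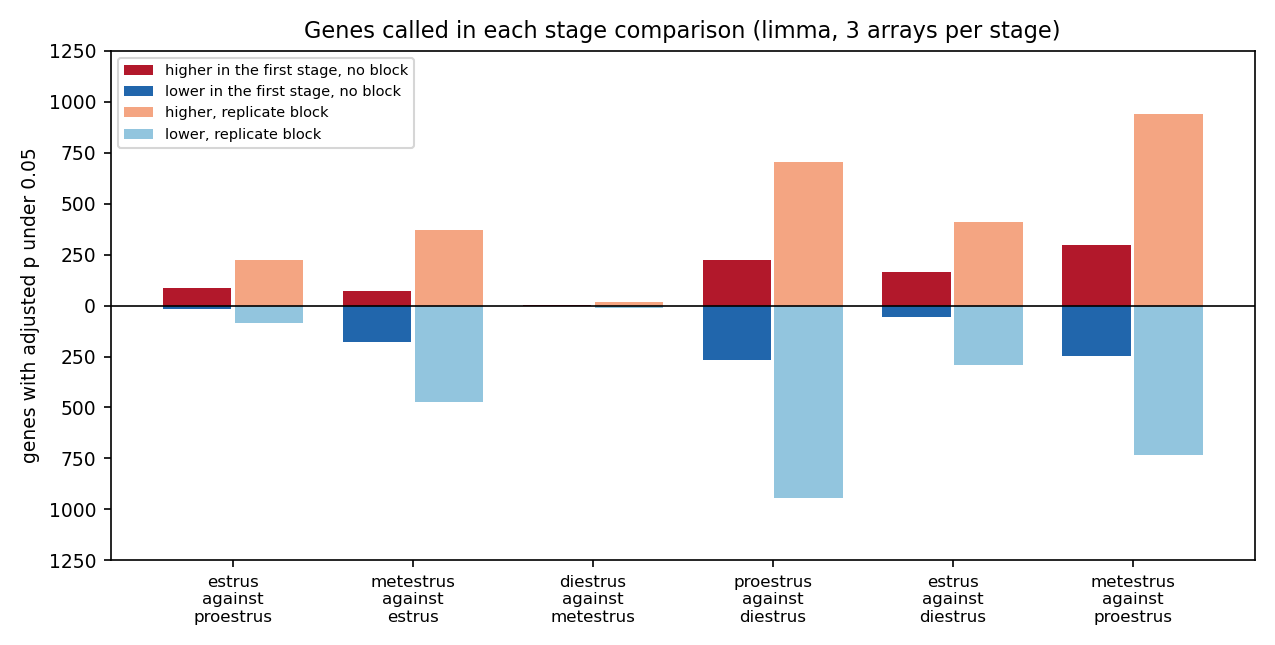
Number of genes called (vertical axis) in each of the 6 stage comparisons (horizontal axis), higher in the first stage above 0 and lower below it, without a block (dark bars) and with the replicate block (light bars). The counts without a block range from 7 for diestrus against metestrus to 541 for metestrus against proestrus.

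Across opposite sides of the cycle, the largest rises at estrus against diestrus were those of Mgarp, Prss35, Akr1c18 and Akr1cl. Mgarp was 13.4-fold higher at estrus (3.75 ± 0.18, adjusted p = 5.1e-07), Prss35 12.1-fold (3.60 ± 0.18, adjusted p = 7.4e-07), Akr1c18 11.8-fold (3.56 ± 0.15, adjusted p = 1.6e-07) and Akr1cl 9.20-fold (3.20 ± 0.13, adjusted p = 1.6e-07, with 2.11 by its second probe). Cyp2j11 and Ano2, undetected at estrus, were at least 4.88-fold and 1.80-fold lower there than at diestrus. Il17rb was 2.82-fold lower (SE 0.14, adjusted p = 1.7e-04) and Gbp5, an interferon-induced GTPase gene detected on 1 of 3 estrus arrays, was lower too (adjusted p = 0.016). The call of Gbp5 was lost without estrus replicate 2 (adjusted p = 0.081) or 3 (0.066) and without diestrus replicate 1 (0.071), 2 (0.059) or 3 (0.051).

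At estrus against diestrus, 8 of 15 ovarian genes were higher, with a median of 1.11, or 0.70 with bounds (camera adjusted p = 7.6e-21), and 6 of 15 oocyte genes, with a median of 1.03, or 0.77 with bounds (camera adjusted p = 5.1e-09). Beside them, 5 of 25 cell cycle genes were higher with a median of 0.42 (camera adjusted p = 5.0e-11), 7 of 19 estrogen-induced genes were higher and 1 lower with a median of 0.45 (camera adjusted p = 1.2e-08), and 2 of 18 cholesterol genes were higher with a median of 0.52 (camera adjusted p = 3.8e-09). Erythrocyte genes had a median of 0.73 with 1 of 5 higher (camera adjusted p = 2.8e-04), and steroid receptors and metabolism one of 0.14 with 3 of 20 higher (camera adjusted p = 0.0044). Over the alternatives the medians ran from 0.42 to 1.86 for ovarian, 0.57 to 1.29 for oocyte and 0.37 to 0.90 for erythrocyte genes. These 7 held with an estimated correlation, but the steroid list was lost when genes had to be detected on all arrays (adjusted p = 0.15) and in replicates 2 and 3 alone (0.075). For the others the highest adjusted p over the camera and fry alternatives was 0.0019 for ovarian, 0.0024 for cholesterol and 0.016 for estrogen-induced genes. It was 0.027 for each of the oocyte, cell cycle and erythrocyte lists.

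Further list results at estrus against diestrus passed only with the preset correlation. The neutrophil median was 0.27 with 1 of 14 higher (camera adjusted p = 0.0059, but adjusted p = 0.32 with an estimated correlation), and the adipocyte median 0.21 with 1 of 11 higher (camera adjusted p = 0.020, but adjusted p = 0.11 with an estimated correlation). Ion and water transport had a median of 0.12 with 4 of 21 higher (camera adjusted p = 0.025, but adjusted p = 0.24 with an estimated correlation). Motile cilia genes were lower with a median of -0.11 and 1 of 24 lower (camera adjusted p = 0.022, but adjusted p = 0.21 with an estimated correlation), as were clock genes with a median of -0.27 and 0 of 14 past the test (camera adjusted p = 0.041, but adjusted p = 0.15 with an estimated correlation). The progesterone-induced list had a median of -0.18 with 1 of 11 lower (camera adjusted p = 0.044, but adjusted p = 0.16 with an estimated correlation) and was lost with the replicate block (adjusted p = 0.053). Its median ran from -0.35 to -0.04 over the alternatives. With 1 array left out, calls were lost for the progesterone-induced list without proestrus 1 (0.061), diestrus 1 (0.13), estrus 2 (0.14), metestrus 2 (0.058) or diestrus 3 (0.055), and for cilia without estrus 1 (0.065) or diestrus 3 (0.062). They were also lost for clock genes without estrus 1 (0.097), estrus 2 (0.061) or diestrus 2 (0.15), for ion and water transport without metestrus 1 (0.052) or diestrus 1 (0.11), and for adipocyte genes without estrus 2 (0.066) or diestrus 3 (0.071).

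In all, 225 genes differed between estrus and diestrus, 167 higher and 58 lower at estrus. The count was 700 (408 higher, 292 lower) with the replicate block, 619 in replicates 2 and 3 alone and 38 (36 higher, 2 lower) from the deposited values without a block. It was 110 without estrus replicate 2, 118 without estrus replicate 3, 143, 122 and 131 without diestrus replicates 1, 2 and 3, and 347 without metestrus replicate 1.

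Metestrus differed from proestrus more widely than any other pair of stages in the fit to all arrays. Aqp8 was 8.83-fold lower at metestrus (SE 0.12, adjusted p = 1.6e-07), Arg1 8.12-fold (SE 0.14, adjusted p = 3.2e-07), Inhba 4.86-fold (SE 0.22, adjusted p = 1.2e-04) and Prss29 4.40-fold (SE 0.28, adjusted p = 9.5e-04). Cyp2j11 was at least 6.24-fold higher and Ano2 at least 2.67-fold higher, both undetected at proestrus. Serpina1d was 5.29-fold higher (2.40 ± 0.11, adjusted p = 3.1e-07) and Serpina1b 5.21-fold (2.38 ± 0.21, adjusted p = 8.3e-05), and which family member these probes read is uncertain. Of the lists, 5 of 18 cholesterol genes were lower with a median of -0.64 (camera adjusted p = 7.3e-12), 8 of 19 estrogen-induced genes were lower and 1 higher with a median of -0.41 (camera adjusted p = 3.3e-06), and 6 of 20 steroid receptor and metabolism genes were lower with a median of -0.27 (camera adjusted p = 6.8e-04). These 3 held with an estimated correlation. Their highest adjusted p over the camera and fry alternatives was 0.0019 for cholesterol, 0.027 for estrogen-induced and 0.029 for steroid genes. The cell cycle median was -0.23 with 0 of 25 past the test (camera adjusted p = 0.0044, but adjusted p = 0.22 with an estimated correlation).

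In all, 541 genes differed between metestrus and proestrus, 295 higher and 246 lower at metestrus. The count was 1670 (939 higher, 731 lower) with the replicate block, 944 in replicates 2 and 3 alone, 27 (12 higher, 15 lower) from the deposited values without a block and 192 (88 higher, 104 lower) with only the 6 arrays of these stages. It was 302, 318 and 357 without proestrus replicates 2, 3 and 1, and 335 and 358 without metestrus replicates 2 and 3. In all 6 comparisons, each called gene had non-overlapping arrays in the compared stages. Among all genes the share without overlap ran from 5.98% for diestrus against metestrus to 24.7% for proestrus against diestrus. Chance would give 10% if the 6 arrays of a pair were interchangeable. Each stage holds 1 array of the differing replicate 1 set, so the shares cannot be read against that value.

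Members of the lists on epithelial function changed across the cycle in part. Of 17 secretory epithelium genes, 4 changed over all genes and 6 adjusted over the list alone: Upk1a, a uroplakin, and Krt7, an epithelial keratin, were highest at proestrus, 2.37-fold and 2.03-fold above metestrus, Slpi was highest at estrus and the tight junction gene Cldn4 at diestrus. Of 24 motile cilia genes, 0 changed over all genes and 0 adjusted over the list alone in limma, and 2 did with the replicate block, Ccno (limma moderated F, adjusted p = 0.0040) and Rfx2 (0.046), both regulators of multiciliated cells, with ranges over the stages of 0.61 and 0.34. Of 22 chaperone and secretory machinery genes, 1 changed and 3 did adjusted over the list alone, the first being Syvn1, a ubiquitin ligase of the endoplasmic reticulum, 1.59-fold higher at diestrus than at proestrus. That call was lost without proestrus replicate 1 (adjusted p = 0.10), 2 (0.072) or 3 (0.087) and with the arrays scaled to a common median (0.10). Of 21 ion and water transport genes, 7 changed and 8 did adjusted over the list alone, among them Aqp8, Aqp5, Car12 and Slc26a4. Of 17 retinoid genes, 4 changed and 5 did adjusted over the list alone: Lrat, Crabp2 and Cyp26a1 were highest at proestrus, while Stra6, a retinol transporter, was highest at metestrus. The call of Cyp26a1 was lost with 11 of the 12 arrays left out in turn (adjusted p up to 0.20) and that of Crabp2 with 7 (up to 0.090). That of Stra6 was lost under 3 of 26 alternatives.

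Of 19 estrogen-induced genes, 10 changed and 12 did adjusted over the list alone, and of 11 progesterone-induced genes, 7 changed and 8 did adjusted over the list alone. Of 20 steroid receptor and metabolism genes, 8 changed and 10 did adjusted over the list alone, among them Hsd17b2, which inactivates estradiol, and the estrogen receptor beta gene Esr2, which was higher at estrus, where it was detected on 3 of 3 arrays, than at proestrus, where it was detected on 1 of 3. In every replicate Esr2 and Hsd17b1 were highest at estrus and lowest at metestrus, as were the ovarian markers Inha and Nr5a2. Whether these members of the steroid list changed in oviduct cells or with ovarian RNA was not tested. Of 18 cholesterol genes, 4 changed and 14 did adjusted over the list alone, and of 25 cell cycle genes, 4 changed and 7 did adjusted over the list alone, with Prc1, Birc5, Bub1b and Mcm5 all highest at estrus and lowest at diestrus. The calls of Cyp51 and Mcm5 were each lost with 9 of the 12 arrays left out in turn (adjusted p up to 0.10 and 0.097), and that of Bub1b without estrus replicate 2 (0.11) or 3 (0.094) or diestrus replicate 2 (0.066). With the replicate block, 13 estrogen-induced, 8 progesterone-induced, 10 steroid, 15 cholesterol and 13 cell cycle genes changed. Of 26 growth factor genes, 7 changed and 11 did adjusted over the list alone, and this list had no list result in the fit without a block. Its members went both ways, with Inhba, Igf1 and Igfbp2 highest at proestrus and Wnt7a highest at diestrus, 2.05-fold above proestrus.

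Of 22 innate defence genes, 5 changed and 7 did adjusted over the list alone, among them Lcn2, the antimicrobial peptide gene Camp, and the complement gene C2, highest at metestrus. Of 21 interferon genes, 3 changed and 9 did adjusted over the list alone, namely Rsad2, Ifit3 and Isg15 over all genes, of which Ifit3 was lost with 8 and Isg15 with 9 of the 12 arrays left out in turn (adjusted p up to 0.16 and 0.11). Of 30 matrix genes, 4 changed and 6 did adjusted over the list alone: Fbln2 was highest at proestrus, 3.06-fold above metestrus, Fbln1 was highest at metestrus, 2.30-fold above proestrus, Mmp3 was highest at diestrus and the protease inhibitor Timp1 at estrus. The call of Timp1 was lost without estrus replicate 2 (adjusted p = 0.101) or 3 (0.096), and that of Mmp3 without proestrus replicate 1 (0.052) or 3 (0.065) and in replicates 2 and 3 alone (0.074). With the replicate block, 10 innate defence, 15 interferon and 14 matrix genes changed. Of 19 immediate-early and stress genes, 5 changed and 6 did adjusted over the list alone, with Dnajb1 and Ccn2 lowest at proestrus and Ccn1 and Ier3 highest there. Ccn1 was lost without any 1 of the 3 proestrus arrays (adjusted p up to 0.078), in replicates 2 and 3 alone (0.059) and with its probes averaged (0.067), and Ier3 with 7 of the 12 arrays left out in turn (up to 0.099). Dnajb1 and Ccn2 were each lost under 2 of 26 alternatives. Of 14 clock genes, 1 changed, Dbp, 1.71-fold higher at diestrus than at proestrus, and 2 did adjusted over the list alone. The call of Dbp was lost without proestrus replicate 2 (adjusted p = 0.057) or 3 (0.059). The time of day of collection is not given in the sources used here, so for clock genes stage and time of day cannot be told apart. Of 16 prostaglandin, endothelin and contractility genes, 1 changed, Edn2, and 2 did adjusted over the list alone, and of 29 antioxidant genes, 2 changed, Gpx1 and Sod3, with the same number adjusted over the list alone. Gpx1 was lost without proestrus replicate 2 or 3 (adjusted p = 0.103 and 0.102) and with scaling to a common median (0.073), and Sod3 with 7 of the 12 arrays left out in turn (up to 0.084). Of 15 smooth muscle genes, 0 changed by either count in limma and 1 with the replicate block, Myh11 (limma moderated F, adjusted p = 0.037). None of the last 3 lists, the immediate-early list or the growth factor list had a list result in any comparison in the fit without a block.

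Among the markers of other cells, 10 of 15 ovarian genes changed and 11 did adjusted over the list alone, with Akr1c18, Cyp11a1, Inha and Nr5a2 all highest at estrus. Of 15 oocyte genes, 9 changed and 13 did adjusted over the list alone, and Nlrp14, Ooep, Bmp15 and Bcl2l10 were highest at estrus. The cumulus matrix list had 3 tested genes, too few for a list test, and 1 changed, Star, which carries cholesterol into mitochondria, detected on all 3 estrus arrays and on 0 of the 3 proestrus arrays. The call of Star was lost under 9 of the 25 alternatives run for it. Of 11 adipocyte genes, 3 changed and 4 did adjusted over the list alone, with Adipoq and Cidec highest at estrus and Pparg at proestrus. The calls of Adipoq and Pparg were lost under 7 and 2 of 26 alternatives. Of 14 neutrophil genes, 2 changed and 5 did adjusted over the list alone, and of 18 macrophage genes, 2 changed, Cd14 and F13a1, by either count, but these calls were lost with 11 and 9 of the 12 arrays left out in turn (adjusted p up to 0.18 and 0.13). Of 5 erythrocyte genes, 1 changed and 2 did adjusted over the list alone, and of 16 endothelium genes, 1 changed by either count, Sox18. Among 8 lymphocyte and 13 mesothelium genes, 0 changed by either count in limma, and with the replicate block 0 and 2 did. Lymphocyte, macrophage and mesothelium markers had no list result in any comparison in the fit without a block.

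Over the 28 lists and 6 comparisons, 53 of 168 tests passed with the preset correlation and 27 with an estimated one. These tests are not independent, since the 6 comparisons share the means of 4 stages and the lists share members. Of the tested genes, 9 of 19 estrogen-induced, 8 of 22 innate defence and 5 of 17 secretory epithelium genes were also in another list. With the replicate block 51 passed, and 49 of these were among the 53. The block also brought in motile cilia for proestrus against diestrus (adjusted p = 0.037) and growth factors for diestrus against metestrus (adjusted p = 0.045). With both the block and an estimated correlation 21 passed, and these 2 were lost (adjusted p = 0.13 for cilia and 0.18 for growth factors). Of the 53 results, 26 kept their call under each alternative run for them. For 7 of these 26, on oocyte and erythrocyte genes, detection on all arrays left too few genes for a test, so that alternative was not run. In 0 of the 53 did the median, the mean and the test differ in sign.

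**Figure D4:**
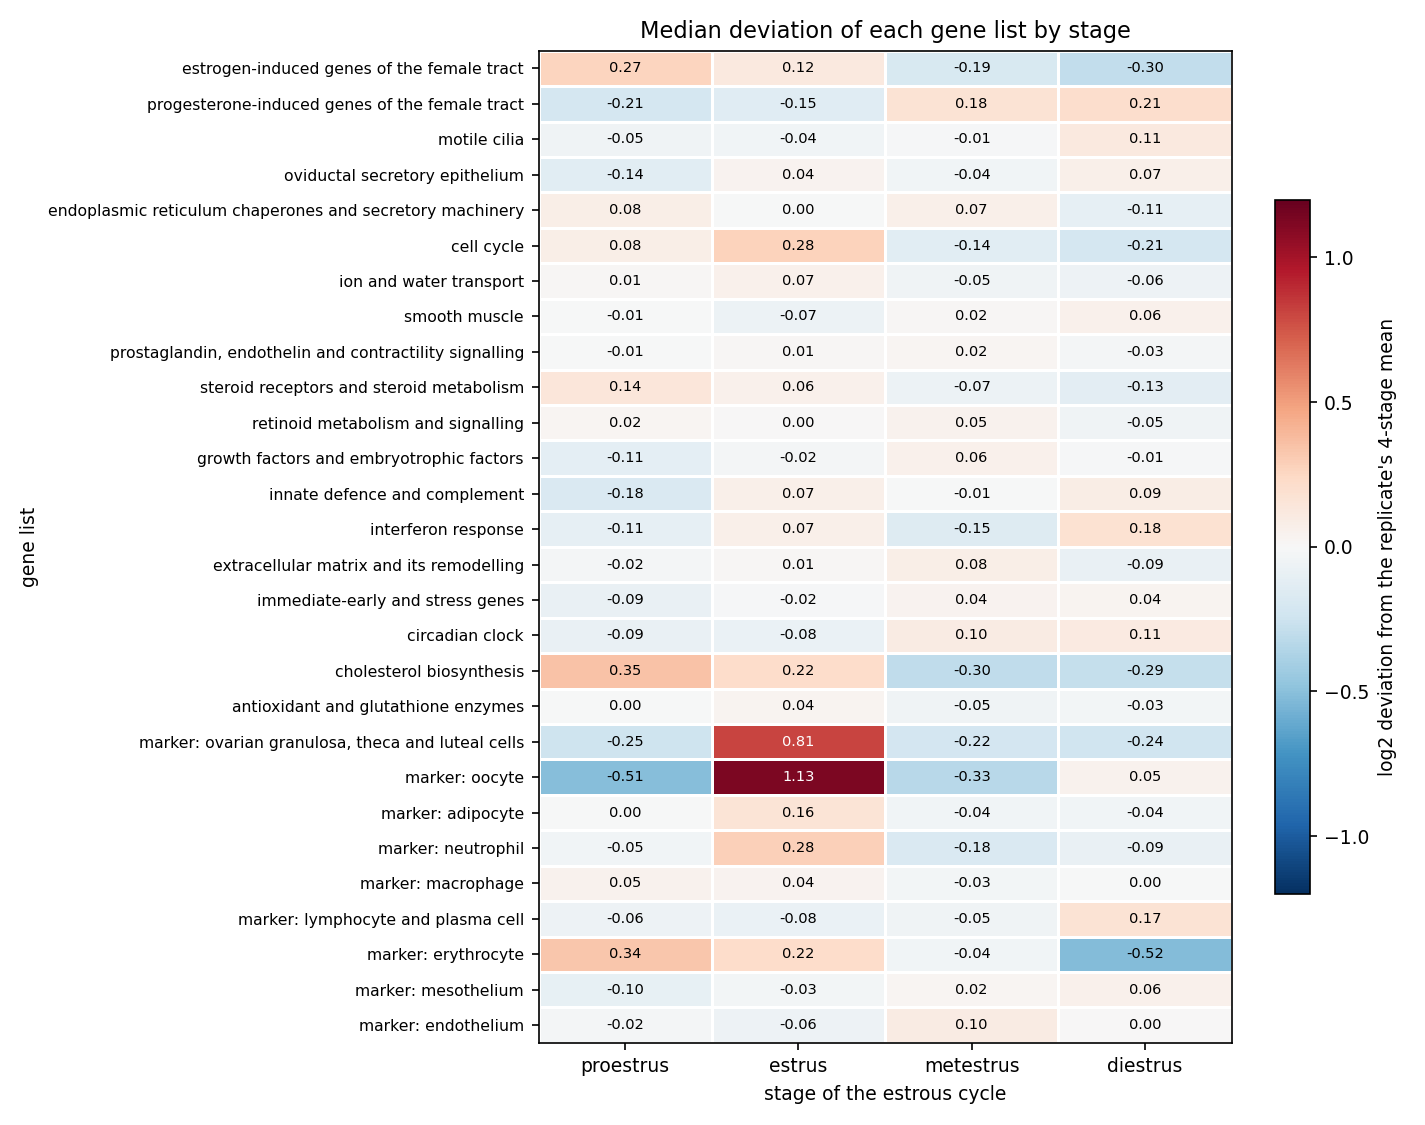
Median log2 deviation of each gene list (vertical axis) in each stage (horizontal axis) from the mean of the 4 stages of the same replicate, averaged over the 3 replicates; red is higher and blue lower. The oocyte and ovarian marker lists stand 1.13 and 0.81 above the mean at estrus, and the cholesterol list 0.35 above it at proestrus.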

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

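Most alternatives were chosen before the data were examined, and 4 were chosen only after results had been seen: the array set as a block, replicates 2 and 3 alone for the counts and for the lists, and the deposited values with the replicate block. A block for the chip, also written down before the data were examined, was not run, since the files name no chip. Where a count moved with the normalization, weights or block, the cause was not tested, except that fewer arrays leave fewer residual degrees of freedom. The deposited values were run with and without the replicate block. Their low counts came only without it, when the difference between their array sets stays in the error. Between 48.6% and 58.1% of probes were detected per array, and requiring detection on all arrays gave 491 of 8315 genes across the cycle.

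Direction and side of the threshold held under every alternative run for 46 of 71 results on genes named in the comparisons, and for 62 of 71 apart from the deposited values without a block. For genes named across the cycle, whose range over the stages has no direction, the side of the threshold held for 18 and 48 of 80. Detection on all arrays left out 19 of the 71 and 10 of the 80, which were not tested that way. None of the 71 results reversed. Of the 62 cycle genes that did not hold everywhere, 30 differed only with the deposited values without a block. Among the rest, Cd14 and Cyp26a1 were lost with each of 11 arrays left out, Isg15, F13a1, Cyp51 and Mcm5 with 9 and Ifit3 with 8. Sod3, Ier3 and Crabp2 were lost with 7, Star with 6, and Adipoq and Camp with 5, and without proestrus replicate 2 or 3, 18 of the 80 were lost each time.

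Genes changed across the cycle, 545 in the fit to all arrays, were 67 from the deposited values without a block and 2891 with array weights. Those 2 settings gave 31 and 1211 for estrus against proestrus (103), 53 and 1259 for metestrus against estrus (250), 0 and 38 for diestrus against metestrus (7), 20 and 1828 for proestrus against diestrus (493), 38 and 809 for estrus against diestrus (225), and 27 and 2688 for metestrus against proestrus (541). The array weights gave replicate 1 arrays 0.14 to 0.39. The 0 came from limma, with 54 unadjusted p-values under 0.05.

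With the replicate block the counts, in the same order, were 1659, 310, 847, 30, 1649, 700 and 1670. The array set as a block gave 1886, 345, 966, 34, 1795, 813 and 1827. The deposited values with the replicate block gave 1444, 265, 765, 15, 1429, 595 and 1464. The ratio of distances between stages to those within, 1.202, was 2.38 with the replicate block.

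Replicates 2 and 3 alone gave 1082, 186, 475, 9, 1292, 619 and 944. Only the 6 arrays of the stages compared gave 98 for metestrus against estrus, 0 for diestrus against metestrus (206 unadjusted p-values under 0.05 in limma) and 192 for metestrus against proestrus. The stage of highest expression was estrus for 58.2% and diestrus for 2.99% of genes called from the deposited values, against 25.1% and 19.6%.

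Leave-one-out gave 345 (without proestrus replicate 2; 351 without proestrus replicate 3) to 664 (without metestrus replicate 1) genes across the cycle. Estrus against proestrus had 57 to 143 (57 without estrus 2, 59 without estrus 3, 64 without proestrus 3). Metestrus against estrus had 147 to 247 (147 without estrus 2, 152 without estrus 3). Diestrus against metestrus had 1 to 13 (1 without metestrus 2 or diestrus 2, 2 without diestrus 1 or 3, 4 without metestrus 3, 13 without metestrus 1). Proestrus against diestrus had 266 to 793 (266 without proestrus 2, 270 without diestrus 2, 283 without proestrus 3, 292 without diestrus 3, 793 without metestrus 1). Estrus against diestrus had 110 to 347 (110 without estrus 2, 118 without estrus 3, 122 without diestrus 2, 131 without diestrus 3, 143 without diestrus 1, 347 without metestrus 1). Metestrus against proestrus had 302 to 543 (302 without proestrus 2, 318 without proestrus 3, 335 without metestrus 2, 357 without proestrus 1, 358 without metestrus 3). List results numbered 47 to 54. The stages held 29.3% to 33.7% (proestrus), 23.9% to 31.3% (estrus), 18.9% to 22.6% (metestrus) and 17.6% to 23.5% (diestrus) of the highest genes. The distance ratio was 1.15 to 1.32 (1.32 without metestrus 1, 1.28 without metestrus 2, 1.29 without metestrus 3).

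Of the 53 list results, 27 passed with an estimated correlation, 46 with fry and 49 with the replicate block, and 16 were lost with 1 or more arrays left out. With the deposited values 42 of the 53 kept their call and 11 lost it, and in replicates 2 and 3 alone 41 kept it and 12 did not. With detection on all arrays 41 kept it, 8 had too few genes for a test, and 4 lost it: interferon response for metestrus against estrus (adjusted p = 0.054), circadian clock for estrus against diestrus (0.058), and steroid receptors and metabolism for proestrus (0.20) and estrus (0.15) against diestrus. The direction of the camera test reversed for 2 lists. For the endoplasmic reticulum chaperones, diestrus against metestrus, it did so without metestrus replicate 1 (median 1.3e-04, adjusted p = 0.97, against -0.24 without metestrus replicate 3, the other end of the range). For the neutrophil markers of the same stages it did so in replicates 2 and 3 alone, although the median there, 0.0218 (adjusted p = 0.90), kept its sign. Without metestrus replicate 1 the neutrophil median was -0.07 (adjusted p = 0.97), while the direction of the test stayed. The steroid list for estrus against diestrus was also lost in replicates 2 and 3 alone (adjusted p = 0.075).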

Other observations

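The tests of the oocyte and ovarian markers and of the replicate 1 batch were chosen only after those results had been seen, and those of the H2 genes and of the array groupings before their values were computed. For 3 of them, the eggs and surrounding cells, Cyp17a1 and the H2 percentile, the rule for reading the value was tightened after the value was known, each time toward leaving the question open. H2-Ke6, a steroid dehydrogenase gene that shares the H2 name, was also left out of the H2 percentile only after its value was known, which left the reading unchanged.

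Whether a random division of the arrays would give such counts was tested for each. Of 100 regroupings of the 12 arrays into 4 groups, the real one included, 1 gave as many as 545 genes, the real one, and the highest other gave 238. These were drawn without regard to the array sets, and most put several replicate 1 arrays in one group, unlike the real one. The count is therefore not a p-value against chance. Of 100 shuffles within replicates with the replicate block, 1 gave as many as 1659, and the highest other gave 536. For each of the 6 pairs of stages, 1 of 10 splits gave as many genes, the real one, and the highest other gave 0, but 10 splits are too few to exclude chance.

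The oocyte and ovarian marker lists were both higher at estrus than at proestrus in each replicate. If eggs and the cells around them had entered the oviduct after ovulation, both lists should rise on every pair of arrays and markers of other tissues should not. The lowest of the 6 list medians was 1.10, which restates the rise, and while 6 of 8 other lists stayed within 0.2 of 0, neutrophil markers stood at 0.33 and erythrocyte markers at -0.23, so this reading stays open. A single array with foreign RNA would let the rise vanish when it is left out, but the lowest oocyte median with 1 of the 6 arrays left out was 1.46. Ovarian tissue taken along with the oviduct might raise the theca gene Cyp17a1, whose log2 difference was -0.21 with a standard error of 0.27. Since Cyp17a1 was already detected at proestrus, this leaves the question open. In each replicate Inha, Nr5a2, Hsd17b1 and Inhba were higher at proestrus, before ovulation, than at metestrus. Inha was at least 7.998 on the proestrus arrays and at most 6.69 on the metestrus arrays. Akr1c18 and Cyp11a1 were lower at proestrus in each replicate. The ovarian list stood at -0.25 from the mean of the stages at proestrus and at -0.22 at metestrus. These values leave the question open too.

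H2-K1 was higher and H2-Ea lower at diestrus than at metestrus by the probes used. For H2-K1 this depended on the probe, with log2 differences of 1.11 by the probe used and 0.21 by its second probe. Fewer antigen-presenting cells at diestrus would lower the other class II genes as well, yet the 6 measured had a median difference of 0.21 with an interquartile range of 0.28, so this reading did not hold. Which family member an H2 probe reads is uncertain, but Cd74, outside that family, had 0.14. The lowest of them, H2-Aa, had -0.80 and the highest 0.41. Sequence differences between animals of an outbred stock could make H2 probes vary within stages. The 17 H2 genes had a median percentile of 42.1 in within-stage spread among genes of the same level, with an interquartile range of 34.9 and 3 genes above the 75th percentile, which leaves that open.

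Replicate 1 arrays stand apart on the first component, and a separate array batch would also show in the unnormalized signal. The dimmest replicate 1 array had 1.33 times the median raw intensity of the brightest other array, which is in line with a separate batch. Whether replicate 1 also came from other animals or another day could not be read from the intensities.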
